A study of Brevibacillus brevis with 6 samples.

How the data were processed

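Expression was measured by RNA sequencing of Brevibacillus brevis KACC10857, with 3 libraries from control cultures and 3 from cultures with a UV-treated polylactic acid (PLA) film. Per the labels' protocols, libraries were made with a stranded mRNA kit with dUTP marking of the second strand and sequenced in pairs of 101 bases. The same protocol speaks of poly A+ RNA, and a step of rRNA removal is not given in the sources used here. Per the submitters' processing notes, Trimmomatic 0.39, HISAT2, featureCounts and edgeR 3.36.0 were used. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here, so antisense or overlapping genes and near-identical copies, such as the 28 rRNA genes, may share reads.

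The deposited table lists 5895 genes with a product name and 1 value per library. Per the file headers the value columns name only the library, and their unit was worked out from the values. The deposited signal values were taken as CPM, counts divided by a library size that the authors had adjusted, since 99.83% to 99.93% of values in each library were whole multiples of the value of 1 read (tolerance 0.01) and all were multiples of 0.5 reads. Sums of the values differ between libraries, so they are not shares of a common total. TMM factors recomputed from the recovered reads gave the same scaling. The authors' deposited log2 fold changes compare PLA with control, and the deposited FDR column holds the adjusted p-values of that test, both per the file headers. The columns of the authors' comparison were used only for the counts of calls named as theirs.

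The design fixed before the data were examined named edgeR's quasi-likelihood test for counts, with limma as its replacement where the file holds normalised values. The file holds normalised values, so limma 3.58.1 in R 4.3.3 was the main test. It was fitted with a mean-variance trend on log2(value + 1) for the 5322 genes with a mean value of at least 1, with group as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. The other 573 genes were not tested. Fold changes on the log2(value + 1) scale understate the change of low genes. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives and called 3396 and 3370 genes. Values of 0.5 reads were rounded for these tests.

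Libraries held 7450897 to 11065353.5 recovered reads, and 3 reads, taken as the floor, amount to 0.164 to 0.657 in the unit of the deposited values. Reads are not independent molecules, so these floors cover counting error only. On simulated data drawn from these libraries' means and sizes for PLA against control, limma recovered 49 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 7 false calls among 156 calls over 5080 genes tested. The changes were set only in genes well above the filter, with a common dispersion for all genes and both groups. The changed genes were also far fewer than the 3439 called in the real data, which makes the adjustment of p stricter. These rates therefore do not cover low genes or the larger spread between PLA libraries. They also do not give the share of 2-fold changes found in the real data. Differences between libraries of a group were above counting noise (chi-square per degree of freedom 4.30 to 184), so no library was counted as a copy of another.

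Gene lists were fixed before the data were examined, as 24 lists matched by product name, because the file gives no symbols. They cover secreted and subtilisin-like proteases; esterases, lipases and cutinases; lactate uptake and oxidation; pyruvate dehydrogenase and gluconeogenesis; the tricarboxylic acid cycle; the respiratory chain; fatty acid beta-oxidation; amino acid degradation; peptide uptake; peptidases inside the cell; flagella and chemotaxis; sporulation; ribosomal proteins; amino acid biosynthesis; purine and pyrimidine biosynthesis; non-ribosomal peptide synthesis; iron uptake; phosphate uptake; chaperones; oxidative stress; DNA repair; S-layer and exopolysaccharide; phage and mobile elements; and anaerobic respiration. Each list with at least 3 tested members was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over 23 lists. For edgeR and DESeq2 the lists were tested with cameraPR, a form of camera that works on the gene statistics, at the same preset correlation. Sporulation stands for spores and mother cells beside vegetative cells, since the culture holds 1 strain.

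Runs of neighbouring genes were counted in the order of the locus tag numbers, which is taken as the gene order, as at least 4 adjacent genes past the threshold with at least a 2-fold change in one direction, and set against 1000 permuted orders. Most genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among named products with a mean log2 value of at least 5 and no overlap of the groups, with at most 2 per run. It adds up to 3 members with the smallest p of each list, up to 8 called members of the protease, esterase and lactate lists, and the first 2 and last named genes of the 4 longest runs in each direction. The transfer-messenger RNA EL268_RS02935 and the list members EL268_RS21600 and EL268_RS03535 lie outside this rule. They and other genes named in the closing section were chosen after their values were seen. Alternatives changed the scaling, the test, the filter, the pseudocount, the most abundant genes, the replicate block, the length of a run and the kind of list test, and left out each library in turn. The figures were drawn with matplotlib 3.10.9.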

Results

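Brevibacillus brevis is a spore-forming, Gram-positive soil bacterium that secretes proteases and peptide antibiotics. Strain KACC10857 was cultured in a mineral medium with soytone and gelatin, either without plastic or with a film of polylactic acid (PLA), a polyester of lactic acid. The film had been cast from solvent and exposed to ultraviolet light. RNA was sequenced from 3 control and 3 PLA libraries, and the labels give the stationary stage for all 6. The comparison asked which transcripts differed in a bacterium described as degrading PLA when the film was present. Expression is given below as the deposited normalised value, as CPM (reads scaled to a common library size), with the library size adjusted by the trimmed mean of M values (TMM), as mean ± SD over 3 libraries per group. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Genes are named by locus tag and product, because the file gives no gene symbols, and no position in the genome is given.

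The control libraries held 8370789, 7450897 and 8057683 reads and the PLA libraries 11065353.5, 9178872.5 and 7454353, as recovered from the normalised values. Stable RNA genes (rRNA, tRNA, transfer-messenger RNA, signal recognition particle RNA, RNase P RNA and 6S RNA) took 44.6% ± 4.49 (SD, n = 3) of the reads in controls and 23.3% ± 6.18 (SD, n = 3) in PLA libraries. The transfer-messenger RNA EL268_RS02935, which rescues stalled ribosomes, alone took 37.3% ± 2.78 (SD, n = 3) and 19.5% ± 4.74 (SD, n = 3). The exact permutation p was 0.1 (two-sided) for both shares, the smallest that 3 against 3 libraries allow. The TMM scaling factors were 0.646 ± 0.0454 in controls and 1.56 ± 0.197 in PLA libraries (SD, n = 3 each). Correlations of log2 values across genes, which are not independent replicates, were 0.991 to 0.992 between control libraries, 0.957 to 0.967 between PLA libraries and 0.756 to 0.792 between the groups.

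**Figure D1:**
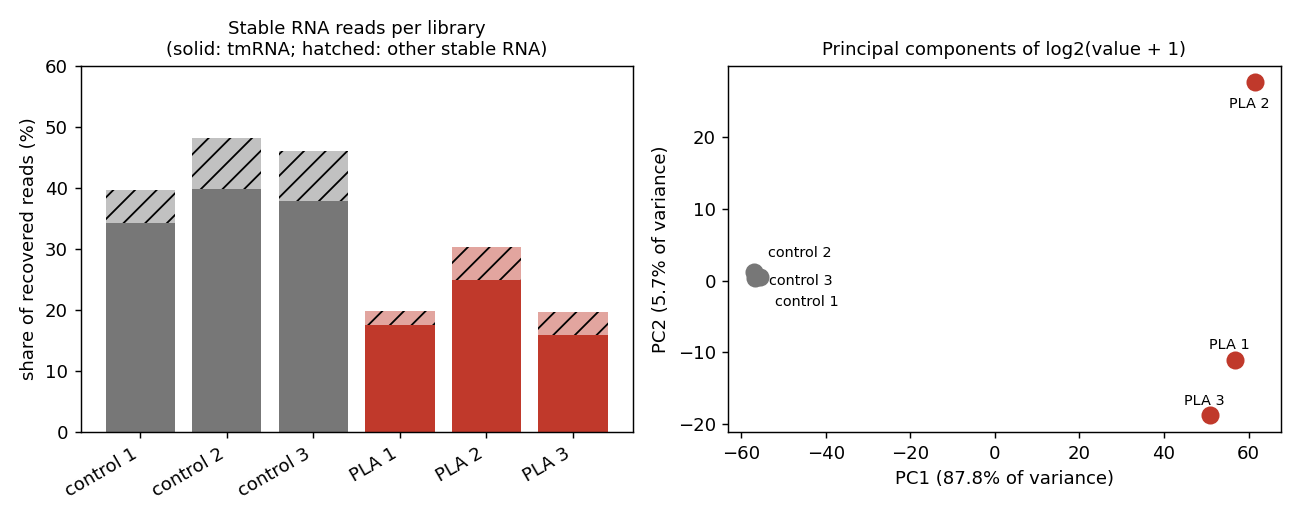
Left, share of recovered reads (%) on the transfer-messenger RNA (solid) and on other stable RNA genes (hatched) in each library; right, the first and second principal components of log2(value + 1) for the 6 libraries. Stable RNA took 39.6% to 48.2% of control reads and 19.6% to 30.4% of PLA reads, and the first component, with 87.8% of the variance, separated the groups.

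With PLA, the lists of ribosomal proteins, flagella, purine synthesis and iron uptake were higher on balance, and those of sporulation, non-ribosomal peptide synthesis and secreted proteases lower. These calls rest on camera with a preset correlation, and each ended with an estimated correlation (adjusted p = 0.423 to 0.762). That form of camera also takes its degrees of freedom from the number of libraries, so with 6 libraries it has little power. For purine synthesis the estimated correlation of 0.00833 lay under the preset 0.01, and the call still ended. The ended calls therefore do not show that correlation between genes explains the list results. Of 5322 tested genes, 3439 passed limma's test at an adjusted p under 0.05, of which 1727 were higher and 1712 lower with PLA. A change of at least 2-fold was seen for 1222 higher and 1184 lower genes. In 71.3% of tested genes the values of the groups did not overlap, where chance gives 10%. The split depends on the scaling: with library totals in place of TMM, 3482 genes were higher and 599 lower, and with the total of genes other than stable RNA, 2894 were higher and 913 lower. Library totals moved the log2 fold change of all genes by a median of 1.19, so directions below are relative to the bulk of genes. The authors' deposited table holds 1862 higher and 1696 lower genes at a false discovery rate of 0.05, and 3335 genes passed in both with the same direction.

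Among named products with a mean log2 value of at least 5, the largest rise was that of EL268_RS28625, an alpha/beta hydrolase, from 23.3 ± 1.48 in controls to 5851 ± 1300 with PLA, a log2 fold change of 7.89 (SE 0.191, limma adjusted p = 2.13e-07). Its neighbour EL268_RS28630, a ring-cleaving dioxygenase, rose from 14.6 ± 2.46 to 2719 ± 966, a log2 fold change of 7.39. EL268_RS20595, a ketoacyl-ACP synthase III, which starts fatty acid chains, rose from 18.9 ± 0.677 to 1195 ± 365. A fatty acid desaturase, EL268_RS26270, which puts double bonds into fatty acids, rose from 16.8 ± 2.40 to 495 ± 41.1. In 1 run of neighbouring genes, the methylmalonyl-CoA carboxyltransferase EL268_RS16005 and the biotin carboxylase subunit EL268_RS15995 had log2 fold changes of 5.40 and 5.05. Close to each other, the peptide transporter substrate-binding protein EL268_RS20900, the asparaginase EL268_RS20905 and the transporter ATP-binding protein EL268_RS20875 had log2 fold changes of 5.72, 5.31 and 4.82. The substrate-binding protein EL268_RS16205 rose by a log2 fold change of 5.63 (SE 0.793, limma adjusted p = 4e-04), but its PLA values were 1064, 187 and 81.8. It stood at 4.60 without PLA library 1 and at 6.44 without PLA library 3.

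The largest fall among the same products was that of EL268_RS26510, a glycosyl transferase, from 1476 ± 69.6 to 21.0 ± 5.26, a log2 fold change of -6.10 (SE 0.196, limma adjusted p = 6.01e-07). Peptide chain release factor 2, EL268_RS02205, which ends translation at stop codons, fell from 11800 ± 376 to 217 ± 57.9, a log2 fold change of -5.80. A non-ribosomal peptide synthetase, EL268_RS03020, fell from 5881 ± 175 to 144 ± 71.7. The neighbouring 3-hydroxyanthranilate 3,4-dioxygenase EL268_RS14770 and amidohydrolase EL268_RS14765 had log2 fold changes of -5.35 and -5.34. The transporter EL268_RS20845 fell from 347 ± 17.3 to 8.49 ± 1.23. Also among the 10 largest falls were 2 extracellular-type proteases and 2 regulators of the forespore, described with their groups below.

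**Figure D2:**
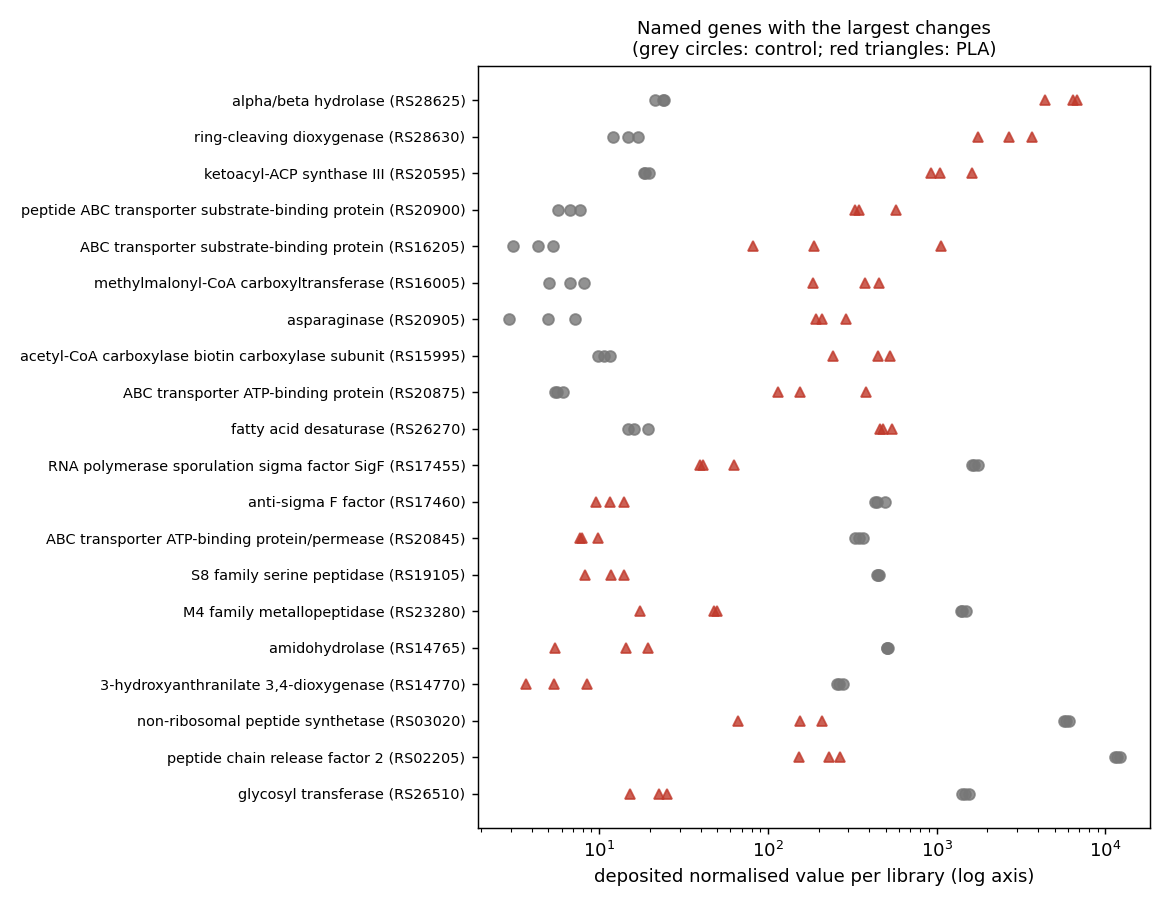
Deposited normalised value in each library (log axis) of the 10 named products with the largest rise and the 10 with the largest fall, with control libraries as grey circles and PLA libraries as red triangles. In each of the 20 genes the 3 PLA values lie apart from the 3 control values, and the PLA values of EL268_RS16205 spread from 81.8 to 1064.

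Ribosomal protein genes were mostly higher with PLA. Of 52 tested, 43 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 1.33 (camera adjusted p = 6.28e-08; adjusted p = 0.498 with an estimated correlation). The 50S protein L10, EL268_RS01445, rose from 48.0 ± 2.91 to 278 ± 61.2. The 30S protein S4, EL268_RS09305, rose from 148 ± 6.25 to 743 ± 106, and L7/L12, EL268_RS01450, from 26.8 ± 0.837 to 133 ± 21.2. In the purine and pyrimidine list, 11 of 17 tested genes rose and 2 fell, with the same counts adjusted over the list alone (median log2 fold change 2.21, camera adjusted p = 0.00304; adjusted p = 0.423 with an estimated correlation). The PurL subunit of phosphoribosylformylglycinamidine synthase, EL268_RS27115, rose from 93.5 ± 3.04 to 806 ± 34.0, and the amidophosphoribosyltransferase EL268_RS27110, the entry enzyme of purine synthesis, from 43.0 ± 2.79 to 410 ± 25. Stable RNA took a smaller share of reads in the libraries in which these groups were higher, as given above.

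The flagella and chemotaxis list had 44 higher and 7 lower genes among 66 tested, and 44 and 8 adjusted over the list alone (median log2 fold change 1.32, camera adjusted p = 2.27e-05, and adjusted p = 0.449 with an estimated correlation). With library totals 61 were higher and 1 lower (median 2.57). The motor switch phosphatase FliY, EL268_RS12335, rose from 13.6 ± 1.47 to 203 ± 52.9. The rod protein FlgB, EL268_RS12260, rose from 33.1 ± 1.77 to 162 ± 8.41, and the export pore protein FliP, EL268_RS12350, from 6.63 ± 0.517 to 58.2 ± 12.9. Of the flagellar genes, 34 of 37 tested were higher and 1 lower, and of the 7 other genes that are not receptors 5 were higher and 0 lower by limma's test, edgeR and DESeq2, or at an unadjusted p under 0.05. The methyl-accepting chemotaxis proteins, the receptors of chemotaxis, went both ways, with 5 higher and 6 lower of 22, and with library totals 17 were higher and 1 lower. This division of the list was chosen after its values were seen.

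Sporulation and spore coat genes were lower on balance. Of 139 tested, 73 fell and 12 rose, and 72 and 12 adjusted over the list alone, with a median log2 fold change of -0.64 (camera adjusted p = 0.000248; adjusted p = 0.664 with an estimated correlation). The forespore sigma factor SigF, EL268_RS17455, fell from 1678 ± 64.6 to 47.9 ± 12.9, a log2 fold change of -5.13, and its anti-sigma factor EL268_RS17460 from 457 ± 32.3 to 11.8 ± 2.26. SigE, EL268_RS10990, the early mother cell sigma factor, fell from 118 ± 6.64 to 8.79 ± 2.48, and the stage II protein E, EL268_RS00885, from 873 ± 14.9 to 69.7 ± 18.3. The list's median turned to 0.40 with library totals, with 57 genes higher and 30 lower, while the median of all genes was then 1.10.

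Secreted and subtilisin-like proteases, which digest protein outside the cell, were lower on balance. Of 9 tested members, 5 fell and 1 rose, with the same counts adjusted over the list alone (median log2 fold change -0.85, camera adjusted p = 0.0438; adjusted p = 0.423 with an estimated correlation). The M4 metallopeptidase EL268_RS23280 fell from 1434 ± 45.9 to 38.4 ± 18.0 and the S8 serine peptidase EL268_RS19105 from 450 ± 5.44 to 11.4 ± 2.94. A further S8 peptidase, EL268_RS31635, fell from 1912 ± 59.3 to 88.9 ± 47.2, and immune inhibitor A, EL268_RS21065, a secreted metalloprotease, from 2124 ± 66.6 to 126 ± 16.4. EL268_RS18225 rose from 2.27 ± 0.777 to 6.01 ± 1.58. EL268_RS13335 fell from 137 ± 7.01 to 101 ± 18.3, but its log2 fold change of -0.45 turned to 0.81 with library totals. Its call ended without control library 1, 2 or 3 or PLA library 3 (limma adjusted p = 0.144, 0.126, 0.0971 and 0.0690). It also ended with RLE scaling (0.0516), with DESeq2 (0.0910), with the replicate block (0.0599) and with limma without a trend (0.0642). The list also holds 2 phage tail sheath proteins, which are not proteases and did not pass, and its median is the value of one of them, EL268_RS03535. Without them, an alternative chosen after seeing the data, the 7 proteases had a median of -4.07 (camera adjusted p = 0.0213; adjusted p = 0.449 with an estimated correlation), and of -2.81 with library totals, with 3 higher and 4 lower. The median of the whole list was -0.51 without PLA library 1, -1.44 without PLA library 2, -2.46 with a stricter filter of at least 5 in at least 3 libraries and 0.35 with library totals. The whole list's call ended without PLA library 2 (adjusted p = 0.0553) and without stable RNA and the 10 most abundant genes (0.0519).

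Esterases, lipases and cutinases, enzyme classes that include polyester-cleaving hydrolases, went both ways relative to the bulk of genes. Of 41 tested, 12 rose and 14 fell, with the same counts adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 0.909). With library totals 26 were higher and 5 lower (median 1.09). Without mismatched members, such as the phytase family protein EL268_RS31620, 12 of 37 rose and 12 fell (camera adjusted p = 0.981), an alternative chosen after seeing the data. Beside EL268_RS28625, the alpha/beta hydrolase EL268_RS08050 rose from 0.456 ± 0.235 to 13.6 ± 2.14, where 3 reads amount to 0.514 to 0.657 in the control libraries. The alpha/beta hydrolase EL268_RS15350 fell from 138 ± 3.01 to 25.7 ± 7.10, and the GDSL-type esterases EL268_RS22600 and EL268_RS08490 had log2 fold changes of -1.59 and -1.20. EL268_RS10185, EL268_RS20695 and EL268_RS31620 had log2 fold changes of -1.93, -1.35 and -1.62. With library totals the log2 fold change of EL268_RS08490 was 0.01, and the calls of EL268_RS22600 and EL268_RS20695 ended (limma adjusted p = 0.0774 and 0.536). The list of lactate uptake and oxidation matched no product in the file, so it gave no value.

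Genes of the tricarboxylic acid cycle were higher on balance, with 8 of 17 tested higher and 1 lower, and the same counts adjusted over the list alone (median log2 fold change 0.37, camera adjusted p = 0.0457; adjusted p = 0.423 with an estimated correlation). The lower member, EL268_RS21600, is a 3-isopropylmalate dehydrogenase of leucine synthesis. Without it and 2 further members outside the cycle, an alternative chosen after seeing the data, 8 of 14 were higher and 0 lower by limma's test, edgeR and DESeq2, or at an unadjusted p under 0.05 (camera adjusted p = 0.0155; adjusted p = 0.449 with an estimated correlation). Both subunits of succinate-CoA ligase rose, EL268_RS12215 from 45.3 ± 3.39 to 229 ± 42.4 and EL268_RS12220 from 52.9 ± 4.22 to 124 ± 13.7, and the malate dehydrogenase EL268_RS30510 rose from 42.6 ± 6.08 to 165 ± 22.5. The whole list's call ended without control library 1, 2 or 3 (adjusted p = 0.0800, 0.0612 and 0.0622) and with edgeR and DESeq2 (0.106 and 0.107). It also ended with RLE scaling (0.0502), the replicate block (0.0620), the stricter filter (0.0511) and without stable RNA and the 10 most abundant genes (0.0506). With library totals 16 genes of the whole list were higher (median 1.63). All 5 tested genes of pyruvate dehydrogenase and gluconeogenesis fell, over all genes and adjusted over the list alone, among them the E1 alpha subunit EL268_RS15585, with a log2 fold change of -1.25, and the pyruvate carboxylase EL268_RS09695, with -0.59. The list did not pass (median -0.64, camera adjusted p = 0.101), and with library totals its median turned to 0.47, with 2 genes higher, EL268_RS09695 to 0.67 and EL268_RS15585 to -0.01 (limma adjusted p = 0.960). Phosphoenolpyruvate synthase, EL268_RS11075, fell from 9.38 ± 0.943 to 5.72 ± 1.01, a direction that turned with library totals (log2 fold change 0.47) and a call that ended without control library 1 or 2 or PLA library 1 (limma adjusted p = 0.0698, 0.0758 and 0.0548).

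The respiratory chain and ATP synthase list had 9 higher and 11 lower genes of 32 (median log2 fold change 0.05, mean -0.38, camera adjusted p = 0.543), the same adjusted over the list alone. The falls included oxidases that pass electrons to oxygen, with log2 fold changes of -3.53 for EL268_RS23835 and -3.15 for EL268_RS23840, both cytochrome oxidase subunits, and -2.54 for the cytochrome d oxidase subunit EL268_RS06505. In fatty acid beta-oxidation, 13 of 24 fell and 8 rose, the same adjusted over the list alone (median -1.03, or 0.23 with library totals, camera adjusted p = 0.298). The enoyl-CoA hydratase-related EL268_RS10845 fell from 1411 ± 48.2 to 414 ± 61.8 and the acetyltransferase EL268_RS21405 from 1194 ± 39.0 to 307 ± 74.1, while the acyltransferase EL268_RS04090 rose from 193 ± 16.1 to 583 ± 96.8. With library totals 20 genes were higher and 5 lower in the respiratory list, and 8 and 3 in beta-oxidation.

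Amino acid degradation had 9 higher and 5 lower genes of 24, the same adjusted over the list alone (median log2 fold change 0.20, camera adjusted p = 0.298). Both named proline dehydrogenases, the first step of proline breakdown, rose, EL268_RS03905 from 16.03 ± 0.223 to 370 ± 59.5 and EL268_RS25445 from 3.94 ± 0.499 to 63.1 ± 9.90. Peptide and oligopeptide uptake had 11 higher and 9 lower of 24, and 11 and 10 adjusted over the list alone (median 0.67, camera adjusted p = 0.717). The substrate-binding protein EL268_RS27890 rose from 59.7 ± 3.01 to 674 ± 134, and EL268_RS01190 fell from 373 ± 15.0 to 90.0 ± 4.79. Peptidases inside the cell had 9 higher and 12 lower of 31, the same adjusted over the list alone (median -0.13, camera adjusted p = 0.846). The dipeptidase EL268_RS20890 rose from 12.1 ± 0.538 to 197 ± 85.5, while the aminopeptidase EL268_RS30090 and the oligoendopeptidase EL268_RS24065 had log2 fold changes of -2.95 and -2.33. Amino acid biosynthesis had 12 higher and 13 lower of 39, the same adjusted over the list alone (median -0.14, mean 0.11, camera adjusted p = 0.946). Its tryptophan synthase beta subunit EL268_RS17040 and phosphoribosylanthranilate isomerase EL268_RS17045 had log2 fold changes of 2.86 and 3.68. Its largest fall was EL268_RS14770, which acts in tryptophan breakdown. With library totals 20 genes of amino acid degradation were higher, and the higher and lower genes numbered 15 and 4 in peptide uptake, 24 and 2 in peptidases and 27 and 2 in amino acid biosynthesis.

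Genes of non-ribosomal peptide and polyketide synthesis, which make peptide antibiotics without ribosomes, were lower on balance. Of 26 tested, 13 fell and 0 rose by limma's test, the same adjusted over the list alone, and 0 were higher at an unadjusted p under 0.05 or with edgeR or DESeq2 (median log2 fold change -1.26, camera adjusted p = 0.0319; adjusted p = 0.762 with an estimated correlation). The edeine synthetase EdeP, EL268_RS13565, fell from 360 ± 33.0 to 29.3 ± 14.5, and EL268_RS03025, with an adenylation domain, from 2316 ± 27.3 to 113 ± 61.9. The list's call ended with edgeR (adjusted p = 0.101) and the stricter filter (0.0511), and without PLA library 2 it ended (0.135) and the log2 fold change of EL268_RS03025 went from -4.55 to -3.96. With library totals the list's median was -0.03, with 10 genes higher and 7 lower.

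Siderophore and iron uptake had 16 higher and 1 lower gene of 28, the same adjusted over the list alone (median log2 fold change 1.09, camera adjusted p = 0.00376; adjusted p = 0.423 with an estimated correlation). The iron transporter permeases EL268_RS25250 and EL268_RS02880 rose from 1.41 ± 0.116 to 10.4 ± 1.83 and from 14.3 ± 1.43 to 53.8 ± 12.1, while the permease EL268_RS23235 fell from 115 ± 6.53 to 5.46 ± 2.35. The list's call ended with library totals, edgeR and DESeq2 (adjusted p = 0.0622, 0.0535 and 0.0563). With library totals, where more of its genes passed the filter, 29 were higher and 1 lower (median 1.97). Phosphate and phosphonate uptake had 6 higher and 1 lower of 11, the same adjusted over the list alone, with a median log2 fold change of 2.73 that did not pass (camera adjusted p = 0.0898). Without members whose product does not belong to the list, an alternative chosen after seeing the data, 6 of 7 were higher and the list passed (camera adjusted p = 0.00693; adjusted p = 0.449 with an estimated correlation). The phosphate transporter ATP-binding protein PstB, EL268_RS27805, rose from 11.9 ± 1.72 to 244 ± 136, and the transporter EL268_RS11795 from 3.48 ± 0.785 to 29.2 ± 3.63. PstS, EL268_RS27835, rose from 0.702 ± 0.137 to 46.6 ± 30.3, with control values near the floor of 3 reads (0.514 to 0.657). S-layer and exopolysaccharide genes went both ways, with 6 higher and 9 lower of 20 (10 and 6 with library totals), and 6 and 10 adjusted over the list alone (median -0.45, or 0.69 with library totals, camera adjusted p = 0.534). The S-layer homology proteins EL268_RS07115 and EL268_RS22305 had log2 fold changes of -3.37 and -2.17, and the polysaccharide biosynthesis protein EL268_RS21425 of 2.10.

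Stress lists did not pass as a whole. Oxidative stress defence had 6 higher and 10 lower genes of 26 (median log2 fold change -0.32, or 0.92 with library totals, camera adjusted p = 0.494), with the catalase/peroxidase EL268_RS14980 falling from 2420 ± 73.3 to 284 ± 67.2 and the superoxide dismutase EL268_RS24975 from 6004 ± 247 to 1572 ± 231. Its arsenate reductase EL268_RS02000, matched by the word thioredoxin, fell from 7.36 ± 0.157 to 1.54 ± 0.261. Chaperones and ATP-dependent proteases had 2 higher and 1 lower of 10 (median 0.01, mean -0.01, camera adjusted p = 0.886): the trigger factor EL268_RS20775 and GroEL, EL268_RS27595, had log2 fold changes of 0.94 and 0.54, and HtpG, EL268_RS22480, of -1.63, a call that ended with library totals (-0.38). DNA repair had 6 higher and 5 lower of 12 (median 0.17, camera adjusted p = 0.797), with log2 fold changes of 2.93 for RuvA, EL268_RS20375, 1.02 for UvrA, EL268_RS02335, and -1.03 for UvrB, EL268_RS02330, which turned to 0.24 with library totals. Phage and mobile element genes had 11 higher and 10 lower of 39 (median -0.10, camera adjusted p = 0.797), with falls in the transposases EL268_RS25835 and EL268_RS25830 and the baseplate protein EL268_RS24870 by log2 fold changes of -2.76, -3.22 and -2.63. Anaerobic respiration and fermentation had 2 higher and 3 lower of 7 (median 0.22, mean -0.37, camera adjusted p = 0.797), with log2 fold changes of -3.66 for NosL, EL268_RS23650, 2.30 for the arginine deiminase EL268_RS03390 and -1.64 for the nitrate reductase EL268_RS05845. In controls RuvA and the arginine deiminase stood at 0.921 and 0.745, near the floor of 3 reads (0.514 to 0.657). Each of these 5 lists had the same counts adjusted over the list alone. With library totals the higher and lower genes numbered 17 and 4 in oxidative stress, 21 and 6 in phage genes and 4 and 2 in anaerobic respiration, and 8 genes were higher in each of the chaperone and DNA repair lists.

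**Figure D3:**
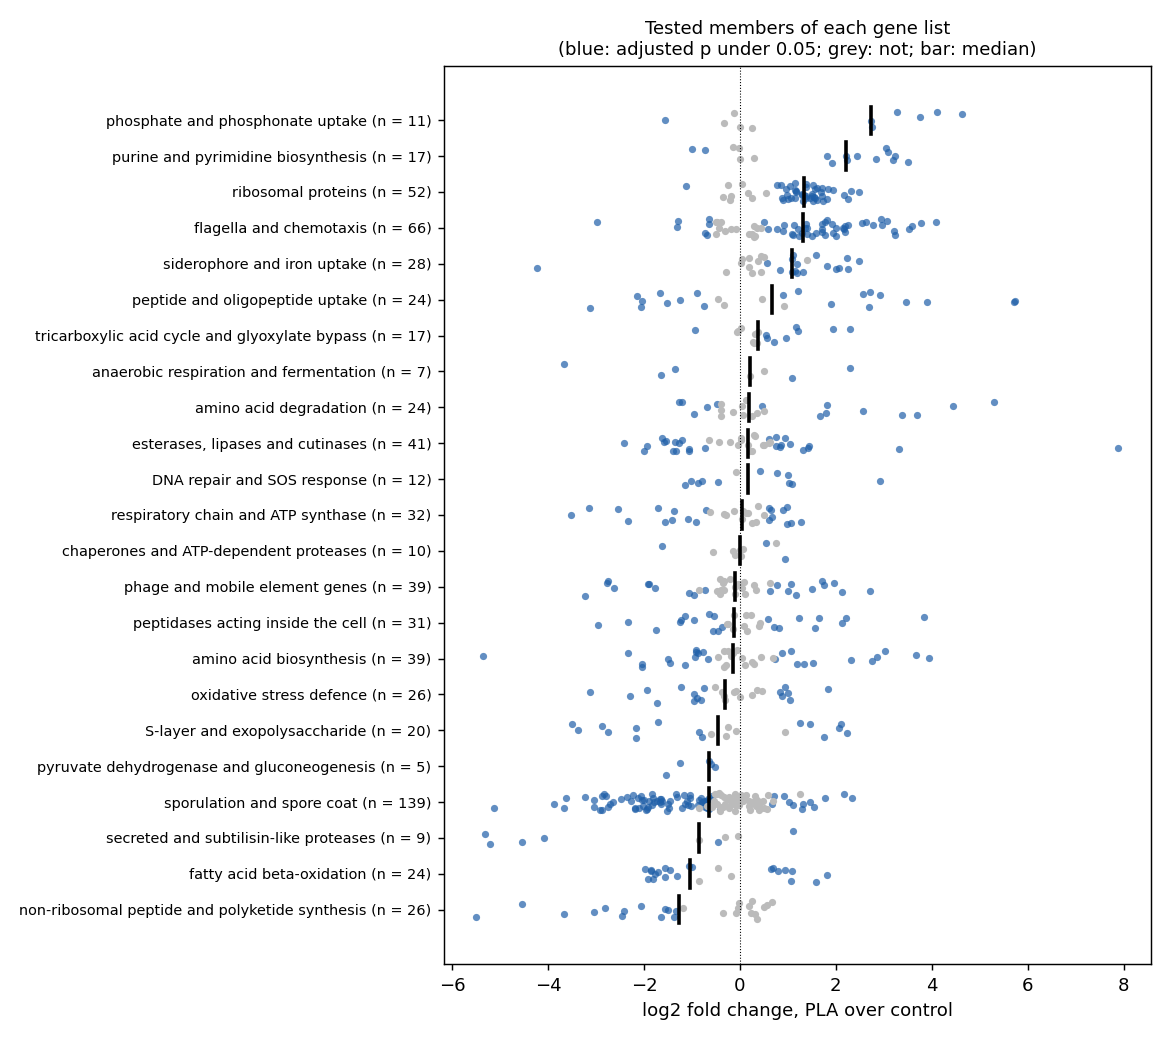
Log2 fold change (PLA over control) of each tested member of the 23 gene lists with at least 3 tested members; blue points passed limma's test at an adjusted p under 0.05, grey points did not, and the bar is the list's median. Medians run from -1.26 for non-ribosomal peptide and polyketide synthesis to 2.73 for phosphate and phosphonate uptake, and with library totals all genes move up by a median of 1.19, which turns each negative median except that of non-ribosomal peptide and polyketide synthesis positive.

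Neighbouring genes changed together. In the order of the locus tags there were 150 runs of at least 4 genes that all passed with at least a 2-fold change in one direction, 73 higher and 77 lower, holding 944 genes. In 1000 permuted gene orders the median was 19 runs and the highest 35 (one-sided permutation p = 0.001, the smallest they can give). The longest run, of 35 higher genes from EL268_RS01495 to EL268_RS01670, holds the main ribosomal protein cluster, with a median log2 fold change of 1.54. Its first genes are a DMT family transporter, EL268_RS01495, with 1.15, and a globin, EL268_RS01500, with 2.51, and its last is the EcfT transporter protein EL268_RS01670, with 1.64. The call of EL268_RS01495 ended without control library 1, 2 or 3 or PLA library 2 (limma adjusted p = 0.0680, 0.0863, 0.0914 and 0.0585), and without PLA library 3 it stood at 0.68 (0.0506). A run of 18 higher genes from FliH, EL268_RS12285, and FliI, EL268_RS12290, to FlhA, EL268_RS12370, had a median of 2.96. A run of 17 from FlgK, EL268_RS02060, and FlgL, EL268_RS02065, to FliD, EL268_RS02140, had a median of 1.78. A run of 14 from EL268_RS12380, a MinD/ParA family protein, and the chemotaxis methylesterase EL268_RS12385 to translation elongation factor Ts, EL268_RS12445, had a median of 1.63.

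The longest lower run held 19 genes, with the endopolygalacturonase EL268_RS08785 and the epimerase EL268_RS08790 as its first named products and the ATP-grasp protein EL268_RS08870 as its last (median log2 fold change -2.49). A run of 16 from a cyclic lactone autoinducer peptide, EL268_RS10155, which fell from 1543 ± 31.1 to 160 ± 84.0, through the antiterminator LoaP, EL268_RS10170, to the cytochrome P450 EL268_RS10235 had a median of -2.38. A further run of 16, with the 2-keto-4-pentenoate hydratase EL268_RS14735 and the 4-hydroxy-2-oxovalerate aldolase EL268_RS14740, enzymes of aromatic ring breakdown, and the tetracycline resistance protein EL268_RS14790, had a median of -3.41. A run of 13 from EL268_RS03015, an Ig-like domain protein, and the synthetase EL268_RS03020 to the transporter permease EL268_RS03075 had a median of -2.70. With 1 library left out, the median of this run ranged from -3.1 to -2.04. With library totals the calls of EL268_RS08785, EL268_RS08870, EL268_RS10170, EL268_RS03015 and EL268_RS03075 ended (limma adjusted p = 0.0788, 0.222, 0.207, 0.290 and 0.947).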

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

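The count tests on recovered reads (edgeR), the scaling by the total of genes other than stable RNA, limma without a trend and lists without mismatched members were chosen after seeing the data. With library totals, 3482 genes were higher and 599 lower, 178 genes were called with the opposite sign and runs numbered 275. With the total of genes other than stable RNA, 2894 were higher and 913 lower, with 13 of opposite sign. TMM sets the bulk of genes to no change by construction, and the cause of the shift under either total was not tested. Under library totals the median log2 fold change became 0.349 for secreted proteases (-2.81 without the 2 mismatched members) and 0.403 for sporulation, and the log2 fold change became 0.669 for EL268_RS09695, 0.475 for EL268_RS11075, 0.238 for EL268_RS02330, 0.808 for EL268_RS13335 and 0.0053 for EL268_RS08490. With the total of genes other than stable RNA it was 0.119 for secreted proteases, 0.200 for EL268_RS09695, 0.0653 for EL268_RS11075 and 0.343 for EL268_RS13335. Of the 112 named genes, 97 kept their call and direction under every setting that tested them (3 failed the stricter filter), and 14 were weaker or turned with library totals. Most of these genes were picked for a large change or a small p in the same data, so their stability is no separate test. Of all 3439 called genes, 2326 kept their call and direction with library totals.

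Gene lists past the threshold numbered 8, and 5 with edgeR, 0 with an estimated correlation (camera, 1 at an unadjusted p under 0.05), 19 with fry, which tests each list by itself, and 9 without mismatched members. For edgeR both the gene test and the list test (cameraPR) differed, and the cause was not tested. With an estimated correlation the degrees of freedom of camera changed as well, so that count does not measure correlation alone. The calls of the ribosomal, flagellar, purine and sporulation lists held in every setting with the preset correlation, and those of the other 4 ended in 2 to 9 settings. Runs numbered 258 at a length of at least 3 and 66 at 6, by construction. Leaving out 1 library gave 2993 to 3535 called genes. With the replicate block, 3368 genes were called, and the tricarboxylic acid cycle list had an adjusted p of 0.0620 and EL268_RS13335 of 0.0599. The deviations of same-numbered libraries correlated at 0.0406, 0.0226 and 0.0341, so the numbers were not taken to pair them, although each of 3 correlated best with its own number. Depth sets a floor: 3 reads amount to 0.164 to 0.657, and 573 genes were too low to be tested. Simulated 2-fold changes, set in genes well above the filter, were recovered for 49 of 100 genes, and the part of depth in this was not tested. Far fewer genes were changed there than in the real data, so this is not the share found here.

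Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 3439 called genes, 2406 with at least 2-fold change, 8 lists and 150 runs. The highest of the others gave 0, 0, 5 and 0 by limma (7 to 35 genes at an unadjusted p under 0.05). For each of these, 1 of 10 splits reached the real value, and 10 splits are too few for a share under 0.05. The other splits also mix control and PLA libraries. The group difference then enters the spread, so their counts do not show what chance gives.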

Other observations

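Several runs of neighbouring genes were chosen after their values were seen, and some of them hold members of the gene lists. A run is defined by all its genes passing in 1 direction, so that all genes of a run changed holds by construction. All 10 genes of a run for ectoine, a compatible solute that protects cells in salt, were lower with PLA, with a median log2 fold change of -4.29. Ectoine synthase, EL268_RS14660, fell from 125 ± 1.66 to 7.39 ± 5.35 and the uptake protein EhuB, EL268_RS14690, from 321 ± 5.20 to 14.7 ± 6.84 (SD, n = 3 each). All 11 genes of a run that holds transporter genes, a regulator and enzymes such as 4-hydroxyproline epimerase were lower (hydroxyproline is abundant in gelatin), with the epimerase, EL268_RS07065, at 25970 ± 480 and 4840 ± 2370. All 8 genes of a run with the edeine synthetase were lower (median -2.04). With library totals the medians of these runs were -3.07, -1.27 and -0.81, and 10 of 10, 10 of 11 and 4 of 8 genes were lower.

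Among further rises, again by the definition of a run, all 9 genes of a methylmalonyl-CoA run were higher (median log2 fold change 4.68). All 9 genes of a run with the general stress sigma factor SigB were higher (median 1.68), with SigB, EL268_RS27705, going from 14.9 ± 0.577 to 67.9 ± 10.8. All 11 genes of an ethanolamine breakdown run were higher (median 1.31). A response regulator, EL268_RS26260, and a sensor kinase, EL268_RS26265, beside the desaturase EL268_RS26270 rose with log2 fold changes of 4.13 and 3.87. An 8-gene peptide uptake run around EL268_RS16205 had a median of 5.18, which went to 4.02 without PLA library 1. Of 39 tested tRNA genes 29 were higher and 0 lower by limma's test, edgeR and DESeq2, or at an unadjusted p under 0.05. For instance, EL268_RS27500, a tRNA-Leu, had a log2 fold change of 2.82. These 39 of 95 listed tRNA genes had a median value of 1.14 in controls and 3.93 with PLA. Some may have passed the filter only through their PLA values, so the count may favour rises. Of 16 genes of 16S and 23S rRNA 14 were lower, for instance EL268_RS28480, a 23S rRNA gene, with a log2 fold change of -3.94.

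All tests of explanations below were chosen after the results were seen. The early sporulation genes were taken as stage II other than protein M, stage III, sigma F, its anti-sigma factor, the antagonist of that factor, and sigma E. Of 16 tested, 15 fell, with a median log2 fold change of -2.95. A stage II protein M, left out of this set, lies in a run of 9 higher genes with log2 fold changes of 1.18 to 2.40. For the 16 genes, the scaling of the libraries as the whole cause is argued against, since their median was still -1.72 with library totals. A more actively growing state of the PLA cultures is a candidate explanation. Translation genes outside the lists had a median of 0.816, with 22 of 34 higher and 4 lower, although peptide chain release factor 2, EL268_RS02205, was at -5.80. Ribosomal protein genes were already known to be mostly higher, so these genes of the same process are little separate evidence. The labels give the stationary stage for both groups, and no sample separates growth state from PLA, so a direct effect of PLA stays open and untested.

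Of 2 separate runs, 1 holds 4 genes from the MarR regulator EL268_RS28400 to the pirin EL268_RS28415. The other holds 5 genes up to the nitroreductase EL268_RS28635. Both runs were higher in all 9 genes, as the definition of a run requires, with a median log2 fold change of 5.58. They hold an azoreductase, a DoxX protein, the hydrolase EL268_RS28625 and the dioxygenase EL268_RS28630, and in Bacillus subtilis genes with several such products are induced by quinones and related electrophiles. The rise did not rest on 1 library, as the lowest median with 1 left out was 5.47, and a like rise of whole families is argued against by the other 57 genes with these product names, at a median of -0.0339 (SD 1.31), although the bound was set after these values were seen and the ranges overlap (highest 3.33, against 1.15 for the lowest of the 9). A general protein-damage response stays open, because the chaperone list had a median of 0.0109 with members going both ways. A reaction to a compound from the film may be proposed as a hypothesis, but it was not tested, and no sample holds solvent or untreated film without the rest.

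Stable RNA took 44.6% of control reads and 23.3% of PLA reads. Size selection that favoured short RNA in controls would lower the long 16S and 23S rRNA genes there. Their median log2 fold change with library totals was -1.88, so they were higher in controls. Poorer rRNA removal in controls would raise these genes and could hide size selection, and the near-identical copies may share reads, so size selection stays open. The rRNA genes took 0.52% ± 0.241 of reads in controls and 0.12% ± 0.0666 in PLA libraries (SD, n = 3 each). Poorer rRNA removal in controls is thus argued against as the cause of more than a small part of the gap in stable RNA. The transfer-messenger RNA, at -0.962 with library totals, makes up most of that gap and is no separate test. A lower content of messenger RNA in control cells would lower tRNA genes with PLA, and these had a median of 1.97 with library totals, but at a median control value of 1.14 they lie near the floor and leave it open. A difference in library preparation that the labels do not record could also give this share and was not tested.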
